A study of Venturia canescens with 6 samples.

How the data were processed

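RNA was measured in heads of newly emerged adult females of Venturia canescens, a parasitoid wasp. Per the labels' protocols, 30 heads were pooled per sample, and RNA was extracted on columns with a DNase step. Polyadenylated RNA was enriched with oligo-dT beads and made into strand-marking libraries (TruSeq Stranded mRNA). There were 6 libraries, 3 from a sexual and 3 from an asexual population, and each was assigned to its population by the group characteristic of its label. The source names of the 6 libraries carry the same sequencing run and lane, so no sequencing batch separates the populations.

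The authors deposited 1 table of raw read counts per gene model for all 6 libraries, with no normalization. The submitters' processing notes name Trimmomatic, HISAT2 and DESeq2, without a role or version. The read counter, its strand setting, the annotation and the genome build are not given in the sources used here. The column names match the ends of the libraries' source names, and 0 columns were left without a sample. The table holds 22333 gene models, numbered with the letter g. Of these, 3449 had no count in any library. The identifiers were looked up in a RefSeq gene table of the species (assembly ASM1945775v1, 14011 genes), and 0 matched. The gene models therefore have no name, product or position here, and a model may be a fragment of a gene or an overlap of several. The 33 product-name gene lists fixed before the data were examined, including markers of other tissues and of reproductive and venom glands, could not be applied, and neither could the planned test of calls along the genome. Since the strand setting of the counting is not given, reads of overlapping and antisense models are not separated here.

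Library totals ranged from 9265064 to 13117716 counts. A single count corresponds to 0.0762 to 0.108 CPM (counts scaled to library size), and 3 counts, the most that a count of 0 allows, to 0.229 to 0.324 CPM. Such limits and the counting intervals given cover counting error only, since reads without molecular identifiers are not independent molecules. The libraries of a population differed by more than sampling noise in every pair (chi-square per degree of freedom 8.96 to 23.4 over genes with at least 10 counts in the pair), so all 6 were kept as separate samples.

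The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) on the deposited counts, with TMM factors, filterByExpr at its default settings and population as the only term. A total of 11700 gene models passed the filter. P-values were adjusted by the Benjamini-Hochberg method, and a model was called at an adjusted p under 0.05. Fold changes are asexual over sexual. Standard errors of log2 fold changes were taken as the fold change divided by the square root of F. Levels are CPM on TMM-scaled library sizes, as mean ± SD of 3 libraries, and correlations and principal components used log2 CPM with a prior count of 2. A model was counted as near absent from a population when it was called, had under 3 counts in each of its 3 libraries and at least 20 in each library of the other population. With no names, the rule for identifiers given in the text was the 2 models per direction with the largest fold change among those called, with a mean of at least 5 CPM and no overlap between populations. This rule, the tests and the alternatives, other than those named below, were fixed before the data were examined.

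The test was tried on counts simulated for the same 11700 models with the comparison's means, dispersions and library sizes and 200 changed models. It recovered 38% of the models changed by 0.5 on the log2 scale, 78% of those changed by 1, 96% of those changed by 2 and 100% of those changed by 4, with 50 models each. Of its calls at an adjusted p under 0.05, 9.83% were unchanged models, a larger share than this threshold aims at. The simulation was run with 200 changed models only, so this share need not hold for the real comparison.

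Replicate numbers are shared by the populations but are not said to mark a common batch, and same-numbered libraries did not deviate together from their population means, so the main fit has no replicate block. The alternatives were other scaling factors, no filter and a stricter filter, a replicate block, leaving out each library, DESeq2 1.42.0, limma-voom, a test against a 1.5-fold change and an adjusted p under 0.01. Leaving out models of sparsely expressed identifier blocks, and leaving out 2 libraries together, were chosen after seeing the data. Permutation and resampling tests used NumPy 2.4.6 with 10000 draws unless stated.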

Results

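Gene expression was measured by RNA sequencing in heads of newly emerged females of the parasitoid wasp Venturia canescens. In sexual populations of this species unfertilised eggs give sons, whereas in asexual populations unfertilised eggs give daughters. Heads of a sexual and of an asexual population were compared, with 3 pools of 30 heads each. Total counts were 10796771, 10827658 and 13117716 in the sexual libraries and 9265064, 10581094 and 10990209 in the asexual libraries. Between 15423 and 16330 of the 22333 gene models had at least 1 count in a library. The most abundant model took 3.71% to 5.50% of the counts of a library and the 10 most abundant took 11.96% to 14.24%. Gene models carry numbers only, so that no gene is named and pathways and cell type markers were not compared.

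The libraries separated by population. Pearson correlations of log2 CPM (counts scaled to library size) across gene models were 0.986 to 0.991 within populations and 0.958 to 0.965 between them, across genes that are not independent replicates. The first principal component held 67.7% of the variance and placed the sexual libraries between -32.8 and -29.1 and the asexual libraries between 30.0 and 33.4. The second component held 13.6% and did not follow population. The biological coefficient of variation was 0.117 among the sexual and 0.105 among the asexual pools, a difference that was not tested.

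The question of the comparison was which genes differ in expression between heads of asexual and sexual females. Of 11700 gene models tested, 1504 (12.9%) differed at an adjusted p under 0.05 by edgeR's quasi-likelihood test, 795 of them higher and 709 lower in asexual females. Most differences were small. The median called model differed by 1.63-fold, and 530 called models (35.2%) differed by more than 2-fold, 258 higher and 272 lower in asexual females. This count was 268 with a filter of 5 CPM in 3 libraries and, in a fit added after seeing the data, 307 without models in identifier blocks where under 25% of the models passed the count filter. Between 4-fold and 16-fold lay 61 models that were higher and 63 that were lower, and 44 and 40 models exceeded 16-fold. The libraries of the populations did not overlap for 1494 of the 1504 called models. Among all tested models, 32.6% had no overlap, where chance gives 10% for 3 against 3 libraries.

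The count of calls depended on single libraries. It was 829 without sexual replicate 3, 834 without asexual replicate 2 and 990 without asexual replicate 1, and the share of calls that were higher in asexual females moved from 52.9% to between 48.0% and 51.1% in these fits. The pools are replicates of 1 sexual and 1 asexual population, so that the p-values measure the spread between pools of these populations and do not separate reproductive mode from other differences between them.

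**Figure D1:**
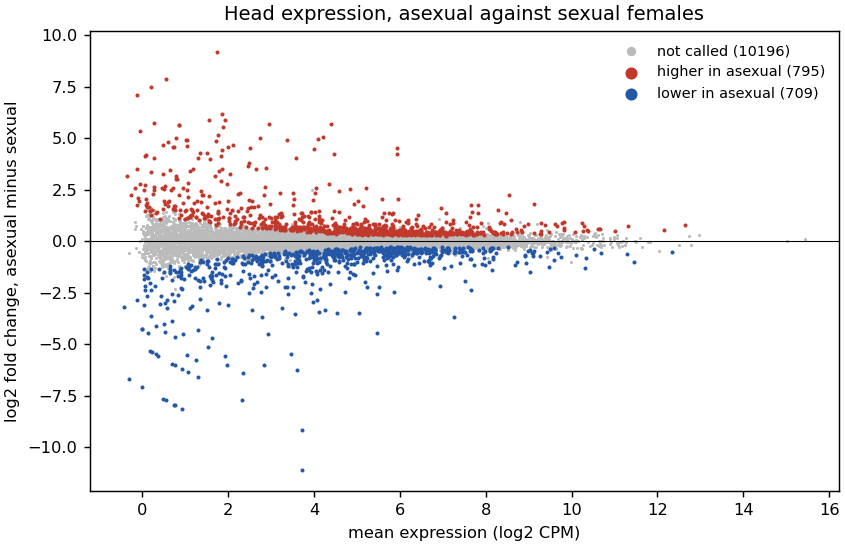
Log2 fold change (asexual minus sexual, y axis) of each of the 11700 tested gene models against its mean expression (log2 CPM, x axis), with 795 models higher in asexual females in red, 709 lower in blue and the others in grey. The widest fold changes lie at low expression, where fitted values of models with no counts in a population depend on the prior count.

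Calls were spread over the whole range of expression, while large changes were concentrated among weakly expressed models. In deciles of the tested models ranked by mean expression, 11% to 14.9% of models were called. In the lowest decile, 174 models differed by more than 2-fold, against 13 in each of deciles 7, 8 and 9 and 25 in the highest. The median absolute log2 fold change of called models was 2.26 in the lowest decile and 0.51 in the highest. Smaller changes were within reach of the test only at higher counts, so these medians compare what was detectable in each decile. In the highest decile 99 models were higher and 71 lower in asexual females.

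**Figure D2:**
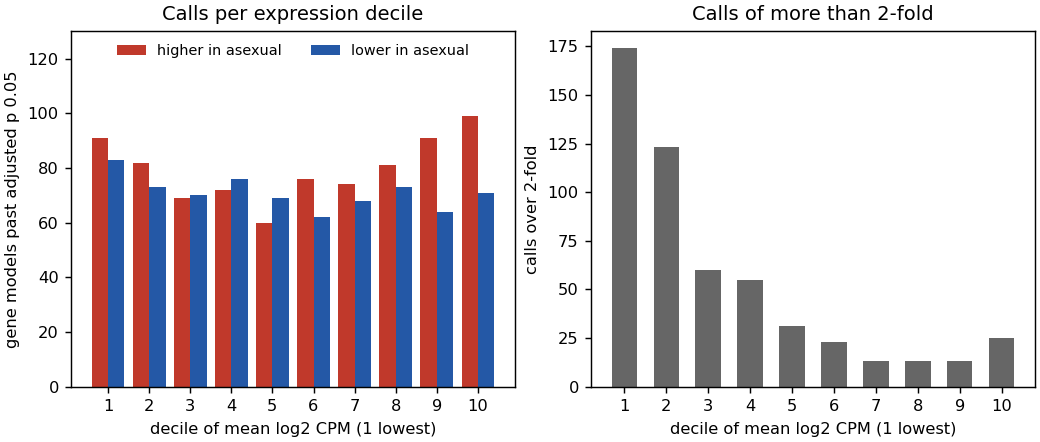
Number of called gene models (left, y axis; red higher and blue lower in asexual females) and of calls over 2-fold (right, y axis) in each decile of the 11700 tested models ranked by mean log2 CPM (x axis). Calls over 2-fold number 174 in the lowest decile and 25 in the highest.

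The shares of counts held by called models are to be read beside their number, 12.9% of the tested models. Models higher in asexual females held 9.75% ± 0.41 of the counts in asexual and 6.35% ± 0.17 in sexual libraries (SD, n = 3). Models lower in asexual females held 4.52% ± 0.16 in asexual and 7.35% ± 0.51 in sexual libraries (SD, n = 3). These models were chosen on the same libraries, so the shares were not tested. Models that were lower by more than 2-fold held 1.70% ± 0.32 of the counts in sexual libraries, and models that were higher by more than 2-fold held 0.86% ± 0.07 in asexual libraries (SD, n = 3). Of the 10 most abundant models, 2 were higher and 1 was lower in asexual females.

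The widest changes by the rule fixed in advance were close to presence against absence. Gene model g20947 had 25.1 ± 9.45 CPM in sexual libraries (SD, n = 3) and 0 counts in each of the 3 asexual libraries, which makes it at least 85.3-fold lower in asexual females against 3 counts per library (edgeR adjusted p = 3.56e-05). Gene model g19658 had 25.1 ± 9.58 CPM in sexual libraries (SD, n = 3), with 890 counts in all, and a single count in the asexual libraries. The ratio of counts, here sexual over asexual and scaled to library size, was 786, with a 95% counting interval of 141 to 31100 (edgeR adjusted p = 1.03e-05). That count was in asexual replicate 1. Without this library no asexual count was left, and with 3 counts assumed in each remaining asexual library, a more cautious limit than the counting interval, the model was at least 89.8-fold lower.

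Among models higher in asexual females, g19706 had 41.6 ± 3.79 CPM in asexual and 0.75 ± 0.73 CPM in sexual libraries (SD, n = 3), a log2 fold change of 5.68 ± 0.31 (SE; edgeR adjusted p = 2.25e-06). Gene model g22032 had 15.4 ± 2.10 CPM in asexual and 0.25 ± 0.44 CPM in sexual libraries (SD, n = 3), a log2 fold change of 5.69 ± 0.50 (SE; edgeR adjusted p = 4.4e-05). Sexual replicate 3 gave 21 of the 28 sexual counts of g19706 and all 10 of g22032. Without it, the log2 fold change of g19706 was 6.93, and g22032 had no sexual count and was at least 55.3-fold higher in asexual females against 3 counts per library.

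**Figure D3:**
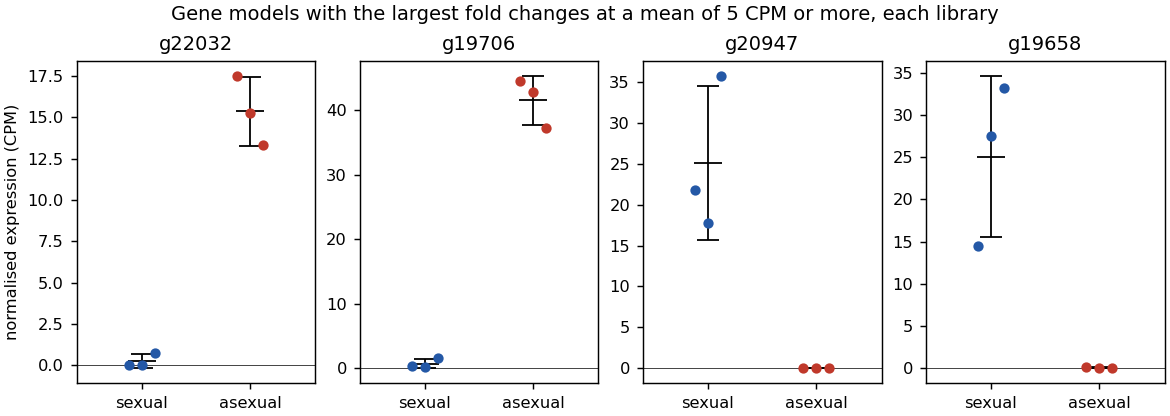
Normalised expression (CPM, y axis) of gene models g22032, g19706, g20947 and g19658 in each of the 3 sexual (blue) and 3 asexual (red) libraries, with black lines for the mean and SD. In g22032 and g19706 the highest sexual point is replicate 3, at 0.757 and 1.59 CPM.

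In all, 23 called models were near absent from 1 population. Asexual libraries lacked 17 of them and sexual libraries 6. The count was 6 with the filter of 5 CPM and 5 without the sparse identifier blocks. The counts also rested on the libraries used. Without asexual replicate 1, 26 models were near absent from asexual libraries, and without sexual replicate 3, 22 were near absent from sexual libraries. Without both, the counts were 27 and 24. Leaving out any library loosens the rule of near absence. With any other single library left out, 17 to 21 models were near absent from asexual and 6 to 7 from sexual libraries. Asexual replicate 1 and sexual replicate 3 both held reads of models that their sister libraries lacked. Over 25 models with at most 1 count in each of asexual replicates 2 and 3 and at least 20 in every sexual library, asexual replicate 1 had 5.22% of the sexual level (95% bootstrap interval over models 2.63% to 8.80%). Over 19 models chosen likewise for sexual replicates 1 and 2, sexual replicate 3 had 6.93% of the asexual level (4.44% to 10.8%). The same measure was 0% to 1.56% in the other 4 libraries, over 5 and 4 models in sexual replicates 1 and 2 and 13 and 14 in asexual replicates 2 and 3. The interval of sexual replicate 1 (0% to 4.37%) overlapped that of asexual replicate 1. The choice of these models allowed at most 1 count in sexual replicate 3 or asexual replicate 1, their sister library, so models with more reads there were left out.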

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

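The number of called models stayed within 1.5 times of 1504 under other scaling factors (1502 to 1535), with no low-count filter (2058), with a filter of 5 CPM in 3 libraries (1186), by limma-voom (1507) and by DESeq2 (1473, of which 1281 were shared with the main calls, all with the same sign). It was 391 in a test against a 1.5-fold change and 706 at an adjusted p under 0.01, both stricter by construction. Leaving out each library in turn gave 829 to 1556 calls, 398 to 773 higher and 411 to 783 lower models, and 23 to 39 near-absent models. The lowest counts came without sexual replicate 3, asexual replicate 2 (834) or asexual replicate 1 (990). Part of any fall comes from having fewer libraries, but leaving out sexual replicate 2 or asexual replicate 3 (1530) raised the count. The small majority of higher calls (52.9%) ended in the fits without sexual replicate 1, 2 or 3, without asexual replicate 3 and without 2 libraries together, and in the test against a 1.5-fold change (49.4%), where 47.0% to 49.7% were higher. DESeq2 called 737 higher and 736 lower. The stricter filter left 268 calls over 2-fold and 6 near-absent models, since it removed weakly expressed models. All 4 gene models given by identifier kept their direction and stayed called in each alternative run on them. With the replicate block, 1165 models were called, 1127 of them shared with the main calls. Same-numbered libraries had correlations of deviations of -0.22, 0.0069 and 0.042, and no library correlated best with its own number. No block along other pairs of libraries was fitted, so a factor shared across the populations by such pairs was not taken out. Added after seeing the data, leaving out models in sparse identifier blocks gave 307 calls over 2-fold and 5 near-absent models. Leaving out sexual replicate 3 and asexual replicate 1 together gave 581 calls, 273 higher and 308 lower, and 51 near-absent models. The planned set tests and the test along the genome were not run, since the models have no names or positions here. Depth limited folds of weakly expressed models, where 3 counts are 0.229 to 0.324 CPM.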

Other observations

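The tests in this part were chosen after the calls had been seen, except those of grouping by sparse blocks, of fold differences within neighbouring pairs and of spread between libraries in sparse blocks, which were set before their results were seen. The second principal component (13.6% of the variance) set sexual replicate 1 (15.5) and asexual replicate 3 (17.6) against sexual replicate 2 (-18.5) and asexual replicate 1 (-17.2). Deviations from the population means correlated across genes by 0.291 between sexual replicate 1 and asexual replicate 3 and by 0.306 between sexual replicate 2 and asexual replicate 1.

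The real split of the 6 libraries gave 1504 called models, 795 higher, 709 lower, 530 over 2-fold and 23 near absent from 1 population. The other 9 splits into 3 and 3 gave at most 0 for each, but each of them puts both populations in 1 group, which widens the spread within groups. With 10 splits, of which only 1 reached the real counts, no share under 0.05 is possible.

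Calls were more frequent in parts of the identifier series. Numbers were cut into 90 blocks of 250, and in 27 of them, at 2001 to 5500 and from 19251 on, under 25% of the models passed the count filter. These sparse blocks held 6583 models, of which 791 were tested and 286 (36.2%) called, 137 higher and 149 lower in asexual females, against 1218 (11.2%) of 10909 tested models elsewhere. The share called was 48.5% at 2001 to 5500 (148 of 305) and 28.4% from 19251 on (138 of 486). The range from 19251 on was cut at 20000 by the share called in its blocks. The share was 14.7% at 19251 to 20000 (23 of 156) and 34.8% from 20001 on (115 of 330), a contrast that follows from the cut. The sparse blocks gave 220 of the 530 calls over 2-fold (41.5%) and 18 of the 23 near-absent models, on 1.80% to 2.58% of the counts of a library. All 4 models given by identifier were also in sparse blocks, with g19658 and g19706 at 19251 to 20000. Low read counts of the sparse-block models are argued against as the cause of the excess over all sparse blocks. Models of the other blocks drawn at the same read level gave 80.7 calls on average and at most 109 in 10000 draws. By range, such draws gave at most 51 calls for 2001 to 5500 and 74 from 19251 on. On either side of the cut they gave at most 54 from 20001 on, and 16.4 on average and up to 32 for 19251 to 20000. As the cut was placed by the calls, these last draws do not test whether the excess ends at 20000. Scatter between libraries regardless of population is not decided as a source of part of the excess. The median SD of log2 CPM within the population with the higher level was 0.22 in sparse blocks. In draws at the same level it was 0.195 on average and at most 0.214. The bound set in advance in favour of scatter, a median SD above every draw, was thus met. However, the main test weighs a difference against the spread between libraries, so a larger SD by itself does not show that scatter added calls. Called models had a median absolute log2 fold change of 1.8 in sparse blocks and 0.607 elsewhere. Also open is the candidate explanation that these blocks hold models on sequence that differs between the populations in presence or copy number, such as repeats, or on sequence to which reads of 1 population map less well. The sequences of the models and the meaning of the numbering were not analysed here, so it was not tested.

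Called models also lay side by side. In table order, 192 pairs of adjacent tested models were called in the same direction, against 96.9 on average and at most 140 in 10000 permutations (one-sided p = 1e-04, the smallest they can give), and 97 pairs were called in opposite directions. Grouping of the sparse blocks does not account for this, since permuting calls within sparse and other models gave 105.7 pairs on average and at most 146. Among pairs 2 to 5 tested models apart, 95 on average shared a direction, within the range of permutations (5th to 95th percentile 89.5 to 104.5). The excess was thus limited to adjacent models in table order. This would bear on long linked blocks of genes only if table order followed the genome, so it does not decide on them. Fold changes within the adjacent pairs were somewhat closer (median difference 0.392 on the log2 scale) than in random pairs of the same direction (0.531, lowest of 10000 draws 0.306), which leaves open that 1 gene split over 2 models or reads shared by 2 models may account for part of the pairs. Table order departs from number order repeatedly. Runs of numbers alternate, as where g6923 follows g15906. Sparse-block models also lie within other runs, as where g3357 lies between g15886 and g15887. Consecutive numbers were held by 136 of the 192 same-direction pairs (70.8%) and by 75.2% of all adjacent tested pairs. Whether table order follows the genome is not stated, and a shared local control of neighbouring genes was not tested.

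Asexual replicate 1 and sexual replicate 3 both held reads of models near absent from the other 2 libraries of their population. The excess extended beyond near-absent models. Over 39 other models whose level in asexual replicates 2 and 3 was under 20% of the sexual level, asexual replicate 1 had a median excess of 7.85% of the sexual level (95% bootstrap interval 3.88% to 11.3%), and over 59 such models sexual replicate 3 had 4.63% of the asexual level (3.62% to 6.11%). The bound first set against mixing was a median excess whose interval ends under the pooled share of the near-absent models. Sexual replicate 3 met it (6.11% against 6.93%), but that pooled share itself had an interval of 4.44% to 10.8%, so the bound was changed after the result was seen and mixing was kept open. Single near-absent models had 0% to 24.7% in asexual replicate 1 and 0% to 38.2% in sexual replicate 3. Whether every near-absent model had the same share is not decided. A chi-square test with 100000 multinomial draws gave p = 1e-05 in both libraries, the smallest the draws can give. That test covers counting error only and not differences between pools in the source level. By the same measure, chi-square per degree of freedom in asexual replicate 1 was 3.68, 6.58 and 11.8 with sexual replicates 1, 2 and 3 as the source. In sexual replicate 3 it was 5.82, 5.92 and 5.49 with asexual replicates 1, 2 and 3. Since the measure covers counting error only, it does not decide which library was the source. Carry-over of RNA or reads, or a few wasps of the other population in each pool, where 1 head of 30 makes 3.33% and 2 heads 6.67%, may each be the source, and these data do not separate them from variation among wasps within a population. Carry-over or foreign wasps would shrink the largest fold changes.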
